A study of Caenorhabditis elegans with 12 samples.

How the data were processed

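Gene expression was measured by RNA sequencing in late-stage embryos of the nematode Caenorhabditis elegans. There were 6 genotypes and 2 libraries per genotype, 12 libraries in all: N2 (the wild type), hpl-2, hpl-2 I158A, lin-61, lin-61 hpl-2 and met-2 set-25 set-32. Genotype and replicate number came from the labels' titles and genotype fields. Per the labels' protocols, frozen embryos were ground and extracted in TRIzol, messenger RNA was selected with oligo(dT) beads, and libraries were made with a directional kit that marks the second strand with dUTP and were read in pairs on an Illumina NovaSeq instrument. Nothing in the labels says whether the replicates of a genotype came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

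The submitters' processing notes name STAR, featureCounts and DESeq2 as tools and WBcel235 and ce11 as genome builds. Their versions and options, the annotation and the strand setting of the counting are not given in the sources used here. The authors deposited a table of normalised read counts (a signal that is never negative) with 1 column per library and 46904 genes, of which 33006 had a read in any library. Each deposited value was a whole multiple of the smallest value of its column, so the signal is the number of reads counted divided by 1 size factor per library. With a tolerance of 1e-06 reads, 100% of the values gave whole reads, and these recovered reads set the depth. The second deposited table holds the authors' own comparisons. Per the file headers, it gives a p-value, an adjusted p-value and a log2 fold change for each gene and pair of genotypes. The authors' log2 fold change was coded there as the first genotype over the second, from its values, and was turned round here. Values from it are named as the authors' deposited table.

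The reads assigned to genes ranged from 1593546 to 2533102 in 11 libraries and came to 10243076 in met-2 set-25 set-32 replicate 2. In N2 replicate 1, the shallowest library, 1 read was worth 1.558 normalised counts. Genes near that level are measured with little precision. A fold against a group with no read in either library is given as a lower bound, against a floor of 3 reads over the group. That bound covers counting error only. Gene symbols and positions came from the Ensembl 115 annotation of WBcel235, matched by WBGene identifier: 46817 identifiers matched and 87 did not. Starts in the deposited comparison table were counted from 0 and were raised by 1, after which 36446 were identical to the annotation. All positions are given on WBcel235 and counted from 1. For 1325 genes the symbol belonged to more than 1 identifier.

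The tests, gene lists and naming rule were fixed before the data were examined, with the exceptions named here. The low-value filter given below, the list test on log2 values in place of counts, and the class tests of lower calls were not in that plan. The plan had been written for counts, with edgeR as the test, and named limma for a table of values divided by size factors. Since the table held such values, the test was limma-trend on log2(normalised count + 1), with all 12 libraries in 1 fit and genotype as the only term, over the 14640 genes with a value of at least 10 in at least 2 libraries. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The residual degrees of freedom were 6 and the prior degrees of freedom 4.73. The comparisons were each mutant minus N2, hpl-2 I158A minus hpl-2, lin-61 hpl-2 minus each single mutant, met-2 set-25 set-32 minus lin-61 hpl-2, and the interaction of lin-61 and hpl-2. The interaction is the double mutant minus both single mutants plus N2 on the log2 scale.

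There were 19 gene lists and 12 families taken by name prefix. The lists were H3K9 and HP1 factors, synMuv B and DREAM factors, P granule and germline genes, small RNA pathway, meiosis, spermatogenesis, oocyte and eggshell, early embryo, cuticle and precuticle, body wall muscle, pharynx, intestine, neurons, cilia, vitellogenins, intracellular pathogen response, innate defence effectors, heat shock and unfolded protein response, and DNA damage and apoptosis. The families were F-box, MATH and BTB, C-type lectins, chemoreceptors, nuclear hormone receptors, collagens by name, cytochromes P450, UDP-glucuronosyltransferases, glutathione S-transferases, major sperm proteins, histones and pals. Of these, 29 could be tested; vitellogenins with 1 measured member and major sperm proteins with 2 could not. Lists were tested with camera at its preset correlation of 0.01 between genes, adjusted over the 29 lists of a comparison, and again with a correlation estimated from the data. Members were also counted with the p-values adjusted over the list alone. Some genes stand in more than 1 list, hpl-2, lin-61 and met-2 among them.

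Genes were named by a rule. For each comparison with N2 it took called genes with a mean CPM of at least 1 over the 4 libraries and both mutant libraries on the same side of both N2 libraries. Among these it took the 6 largest and 6 smallest fold changes with a letters-number symbol and the 3 largest and 3 smallest with any other name. It added the 5 mutated genes and up to 4 called members of each list that passed. For the other comparisons it took the 4 largest and 4 smallest with such a symbol. A gene whose name joins a symbol with an identifier because the symbol is shared is left out of the text. Genes named outside this rule are said to be so.

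Calls on chromosome arms (the outer parts of an autosome against a middle part of the same length as each) and in annotated classes were tested with two-sided Fisher's exact tests with Benjamini-Hochberg adjustment; genes are not independent replicates. Similarity between comparisons was set beside 50 simulations of pairs of unchanged groups that share simulated control libraries. The simulation was changed after its first result to use the spread of the 11-library fit, and a covariance computed from the spread of the N2 libraries themselves was added then.

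The alternatives fixed beforehand were another scaling, DESeq2 on the recovered reads, no filter on low values, a filter on CPM, the replicate number as a block, only the compared genotypes in the fit, an absolute log2 fold change of at least 1, pseudocounts of 0.5 and 5, other bounds for the arms, an estimated correlation for the lists, and leaving out each library in turn. The planned scaling change became TMM in place of the deposited size factors. The planned filter of a CPM of at least 1 in at least 2 libraries turned out looser than the one used, with 22519 genes. Alternatives chosen after seeing the data were edgeR on the recovered reads, a value of at least 20, genes without exons opposite another gene, a class of libraries by mitochondrial read share as a term, 1 N2 library for each mutant of a pair, and leaving out met-2 set-25 set-32 replicate 2 from comparisons that do not involve it. The rules by which the tests of single genes at the left end of X, of age in lin-61 and of strand information in met-2 set-25 set-32 replicate 2 were judged were rewritten after their values were seen. The library class of higher mitochondrial share held both libraries of N2 and of lin-61 hpl-2, hpl-2 replicate 1 and met-2 set-25 set-32 replicate 2. With genotype in the fit, this term rests only on hpl-2 and met-2 set-25 set-32, whose replicates fall in different classes. With a lone library left in a genotype, that library is assumed to vary like the other genotypes.

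The tests were tested on simulated data: counts for the 14640 genes with 200 changed, 50 at each fold. For hpl-2 against N2, limma called 0% of the genes changed 2-fold, 38% at 4-fold, 84% at 8-fold and 90% at 16-fold, and 7.02% of its calls were unchanged genes. For met-2 set-25 set-32 against N2 these shares were 8%, 46%, 80%, 92% and 7.38%. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.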

Results

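Messenger RNA was measured in late-stage embryos of the nematode Caenorhabditis elegans of 6 genotypes, with 2 libraries each. N2 is the wild-type strain. HPL-2 is a homolog of heterochromatin protein HP1, which binds histone H3 methylated at lysine 9 (H3K9), and was studied in hpl-2 mutants and in a strain with the I158A point mutation. LIN-61 is an MBT-repeat protein that binds the same mark, studied alone and in the lin-61 hpl-2 double mutant. The met-2 set-25 set-32 strain carries mutations in H3K9 methyltransferase genes. The series title concerns the phase transition of heterochromatin, and the comparisons ask how expression differs when the readers or the writers of H3K9 methylation are mutated. Values are normalised read counts, given as mean ± SD (n = 2), and the tests are limma tests over 14640 genes.

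The libraries held 1593546 to 2533102 reads assigned to genes, apart from met-2 set-25 set-32 replicate 2 with 10243076. That library stood apart in other measures too. Non-coding RNA genes took 3.2% of its reads and 14.5% to 17.5% in the other libraries, mitochondrial genes took 1.62%, and ribosomal RNA genes took 4.57%. Its score on the first principal component, which held 29.4% of the variance, was 143, against -34.3 to 5.36 for the others. The correlation between replicates across genes was 0.838 in met-2 set-25 set-32 and 0.925 to 0.967 in the other genotypes. The median SD of log2 values between replicates was 0.622 there, 0.297 in N2, 0.229 in lin-61 hpl-2, 0.177 in hpl-2 I158A, 0.165 in lin-61 and 0.157 in hpl-2. Without this library the median residual SD went from 0.458 to 0.314. Each count of genes is therefore also given for the other 11 libraries, a choice made after seeing the data. Mitochondrial read shares of the remaining libraries were 0.327% and 0.344% in N2, 0.446% and 0.104% in hpl-2, 0.103% and 0.0977% in hpl-2 I158A, 0.109% and 0.1% in lin-61, and 0.314% and 0.326% in lin-61 hpl-2. The other met-2 set-25 set-32 library was at 0.0807%.

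Non-coding genes lying opposite the exons of a coding gene over at least 90% of their length held more reads per kilobase than that gene. The median log2 ratio was 3.37 to 4.54 in 11 libraries and 2.14 in met-2 set-25 set-32 replicate 2. Non-coding genes opposite introns had median log2 ratios of 0.361 to 1.215 in the 11 libraries and -1.74 in that replicate. The gap between both kinds was 3.884 there, within the 2.974 to 3.978 of the 11 libraries. Since the strand setting of the counting is not given, a gene and the gene opposite it cannot be told apart with certainty. If reads were counted on the strand opposite to the transcript, levels of coding genes without such an overlap would also rest on reads of the wrong strand. This would hold for the named coding genes too, for which it was not tested. Across the overlapping pairs, log2 fold changes of both genes correlated at 0.674 in hpl-2 I158A against hpl-2, as such counting predicts. Pairs opposite introns also correlated there, at 0.384, so this does not settle the strand. Opposite overlaps above 10% of a named gene are stated beside it.

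Of the mutated genes, hpl-2 (WBGene00001996, III, 10752254 to 10755523) fell in the hpl-2 strain from 273 ± 43.3 to 35.4 ± 1.15 (log2 fold change -2.91, SE 0.254, limma adjusted p = 0.000691). It fell in lin-61 hpl-2 to 40.3 ± 13.4 (-2.76, limma adjusted p = 0.00116) and stood at 263 ± 28.1 in hpl-2 I158A. lin-61 (WBGene00003041, I, 7248828 to 7251422) was at 66.7 ± 35.7 in N2, 6.3 ± 1.2 in lin-61 and 13 ± 0.81 in lin-61 hpl-2. Neither difference passed with all 12 libraries (log2 fold changes -3.11 and -2.16, limma adjusted p = 0.0541 and 0.127). Without met-2 set-25 set-32 replicate 2 both did (limma adjusted p = 0.000355 and 0.00493). met-2 (WBGene00019883, III, 8375300 to 8380833) fell from 267 ± 0.358 to 60.7 ± 23.1 in met-2 set-25 set-32 (-2.17, limma adjusted p = 0.0045). It also fell in hpl-2 I158A, to 42.2% of N2 (-1.24, SE 0.255, limma adjusted p = 0.0287). set-25 (WBGene00012802, III, 13283892 to 13293088) fell from 412 ± 8.25 to 130 ± 42.2 (-1.70, limma adjusted p = 0.0101). set-32 (WBGene00008062, I, 9519244 to 9521275) was at 14.9 ± 1.29 in N2 and 4.91 ± 2.85 in met-2 set-25 set-32, with a log2 fold change of -1.52 that did not pass (limma adjusted p = 0.238).

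**Figure D1:**
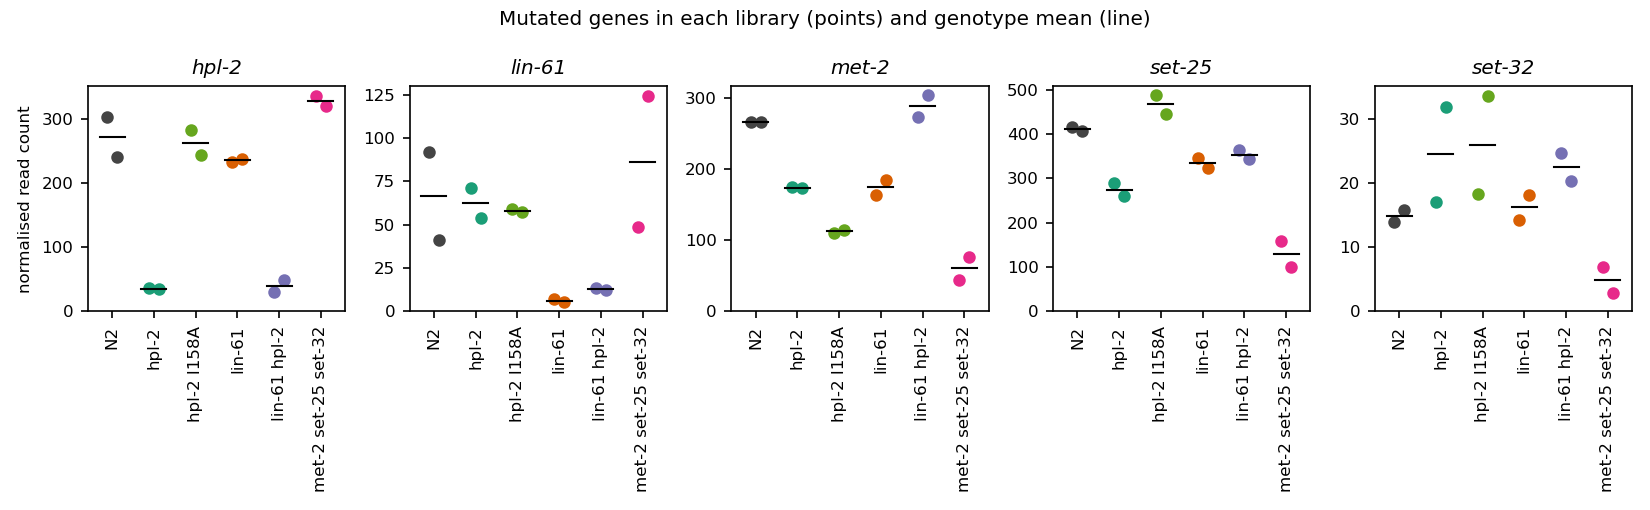
Normalised read counts of the 5 mutated genes, 1 panel per gene and 1 column per genotype; points are libraries and lines are means of 2 libraries. hpl-2 lies at 12.9% of N2 in the hpl-2 strain and lin-61 at 9.45% of N2 in the lin-61 strain.

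C38D9.2 (WBGene00008010, V, 17567513 to 17571603, protein coding) rose in every mutant. It was at 12.9 ± 0.667 in N2 and rose 30.2-fold in hpl-2, 37.3-fold in hpl-2 I158A, 42.4-fold in lin-61, 44.1-fold in lin-61 hpl-2 and 46.6-fold in met-2 set-25 set-32 (SE 0.17 on the log2 scale). The limma adjusted p was 2.36e-07 or lower in each. F15D4.5 and the pseudogene WBGene00014947 were the other genes higher in all 5 mutants. The snoRNA gene F59C6.15 (I, 10516978 to 10517150) was the gene lower in all 5: it stood at 179 ± 11.5 in N2, 2.01 ± 1.48 in hpl-2 I158A and under 1 in the other mutants. lido-18 (III, 7662428 to 7672153) was at 5.21 ± 2.97 in N2 and rose in hpl-2 (12.5-fold), lin-61 (11.6-fold) and met-2 set-25 set-32 (18.2-fold), with limma adjusted p = 0.0047, 0.00876 and 0.00152. Chosen after its values were seen, lido-18 also rose in lin-61 hpl-2, to 87.7 ± 28 (log2 fold change 3.89, limma adjusted p = 0.00277), and it did not pass in hpl-2 I158A (9.46 ± 2.48, limma adjusted p = 0.304). The pseudogene WBGene00023391 (X, 86887 to 86958), wholly opposite WBGene00022205, had no read in N2. It was at least 27.8-fold higher in hpl-2, at least 20.5-fold in hpl-2 I158A, at least 28.2-fold in lin-61 and at least 43.2-fold in lin-61 hpl-2. In met-2 set-25 set-32, where it lies among the genes with few or no reads at the left end of X, it had no read either. F15D4.5 was named after its values were seen. All 5 comparisons use the same 2 N2 libraries. For the genes changed across the mutants, a difference particular to N2 cannot therefore be told apart from a change shared by the mutants.

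In the hpl-2 mutant, which addresses what loss of this HP1 homolog changes, gcy-19 (WBGene00001544, II, 3250985 to 3259354), a receptor-type guanylate cyclase gene, rose 11-fold from 13.5 ± 1.53 (limma adjusted p = 0.00163). spp-5 rose 4.69-fold (0.0402), gba-1, of the glucosylceramidase family, 6.51-fold (0.0479), and the C-type lectin gene clec-10 from 0.609 ± 0.862 to 23.5 ± 5.74 (limma adjusted p = 0.0365). ethe-1, which overlaps a gene on its own strand, was at least 3.58-fold higher. C02E7.6 (V, 4919207 to 4919586) had no read in hpl-2 and 141 ± 67.5 in N2, at least 103-fold lower (limma adjusted p = 1.17e-05). Its neighbour C02E7.7 fell 21.1-fold, to 1.33 ± 1.88 (limma adjusted p = 0.0104). In lin-61 hpl-2, where hpl-2 was also low, they stood at 147 ± 10 and 78 ± 39.9. C02E7.6 lies in a run of 9 neighbouring expressed genes under 50% of N2 in hpl-2 (V, 4892588 to 4919586). Shuffled orders gave runs of at most 5. Whether these falls belong to this strain rather than to loss of hpl-2 was not tested. Among abundant genes, his-24 (WBGene00001898, X, 14490094 to 14491115), a linker histone H1 gene with 18.9% of its length opposite M163.16, fell 2.76-fold, from 9540 ± 150 to 3460 ± 32.2 (limma adjusted p = 0.0365). snr-2, a core spliceosomal protein gene, fell 2.65-fold (0.0212), rbm-39 2.85-fold (0.00727), and the neighbours lido-8 and lido-9 fell 3.66-fold and 2.87-fold (0.0102 each, limma adjusted p; lido-8 overlaps a gene on its own strand).

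Histone genes were the list furthest from the rest in hpl-2. Of 57 measured, 2 fell (his-24 and his-67), and 26 were lower and 2 higher when adjusted over the list alone (median log2 fold change -0.65, camera adjusted p = 5.7e-12; adjusted p = 0.352 with an estimated correlation). Germline and chromatin lists were also lower. For P granule and germline genes, 0 of 24 members were called and 1 was lower adjusted over the list alone (median -0.39, camera adjusted p = 0.000992; adjusted p = 0.547 with an estimated correlation). In the small RNA pathway 1 of 38 fell, the Argonaute gene ergo-1 (993 ± 40.1 to 493 ± 13.8, limma adjusted p = 0.0365), with 4 lower and 1 higher adjusted over the list alone (median -0.24, camera adjusted p = 0.0093; adjusted p = 0.547 with an estimated correlation). H3K9 and HP1 factors had 1 call of 12, hpl-2 itself, and 3 adjusted over the list alone (median -0.60, camera adjusted p = 0.000992; adjusted p = 0.2 with an estimated correlation). For synMuv B and DREAM factors hpl-2 was again the 1 call of 18, with 2 adjusted over the list alone (median -0.41, camera adjusted p = 7.22e-05; adjusted p = 0.547 with an estimated correlation). Heat shock and unfolded protein response genes had 1 of 15 lower, the mitochondrial chaperonin gene hsp-60 (1200 ± 198 to 581 ± 6.76), and 3 adjusted over the list alone (median -0.38, camera adjusted p = 0.0415; adjusted p = 0.547 with an estimated correlation). DNA damage genes (22, median -0.35, camera adjusted p = 0.0093) and F-box genes (146, median -0.28, 0.0377) were lower as lists, and collagens (85, median 0.41, 0.0238), body wall muscle (22, 0.31, 0.0251), pharynx (14, 0.55, 0.0322) and neurons (26, 0.34, 0.0377) higher. In these last 6 lists 0 members were called and 0 when adjusted over the list alone, and the adjusted p was 0.739 for collagens, 0.562 for body wall muscle and 0.547 for the others with an estimated correlation. The 7 lists without a call hold 339 genes, of which 41 had an unadjusted limma p under 0.05, DESeq2 called 1 and edgeR 0.

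In all, limma called 41 genes higher and 48 lower in hpl-2, with 2193 genes at an unadjusted p under 0.05. The total of 89 was 23 without N2 replicate 1, 26 without N2 replicate 2, 8 and 9 without hpl-2 replicates 1 and 2, and 2107 without met-2 set-25 set-32 replicate 2 (829 higher and 1278 lower, with 40 and 48 of the first calls among them). With TMM scaling the split was 33 higher and 26 lower, and with library class as a term 29 were called. Of 21 named calls, those of C02E7.6, C38D9.2, WBGene00023391, gcy-19 and hpl-2 passed with each of these 5 libraries left out. Among the 12 lists that passed, histones, P granule and germline genes, small RNA pathway, H3K9 and HP1 factors, and synMuv B and DREAM factors passed each time, and body wall muscle turned lower without N2 replicate 1 (camera adjusted p = 0.901). The 2 hpl-2 libraries had ribosomal RNA shares of 2.37% and 0.372%, and median histone log2 values over N2 of -0.53 and -0.66.

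The hpl-2 I158A comparison addresses what the point mutation changes while hpl-2 messenger RNA is present. Oocyte and eggshell genes rose: 12 of 27 were higher and 23 adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 1.09e-15; adjusted p = 0.535 with an estimated correlation). cey-3, a Y-box RNA-binding protein gene (WBGene00000474, I, 5571787 to 5573019), rose 3.2-fold, from 256 ± 62.2 to 810 ± 2.02 (limma adjusted p = 0.00468). mex-5, a maternal zinc-finger RNA-binding protein gene (WBGene00003230, IV, 13353723 to 13356104), rose 2.4-fold to 897 ± 16 (0.0136), mex-1 rose 2.49-fold (0.0159) and egg-1, an oocyte surface protein gene, 3.76-fold (limma adjusted p = 0.0161). In P granule and germline genes 1 of 24 rose, pgl-1 (2.16-fold, limma adjusted p = 0.0454), and 4 adjusted over the list alone (median 0.56, camera adjusted p = 6.48e-05; adjusted p = 0.955 with an estimated correlation). Histones had 4 of 57 higher and 6 adjusted over the list alone (median 0.15, camera adjusted p = 0.0193; adjusted p = 0.955 with an estimated correlation). These were his-38, his-59 and the H3.3-type genes his-71 and his-74, the last 2.64-fold higher at 209 ± 8.52 (limma adjusted p = 0.0136).

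Among the genes that fell in hpl-2 I158A were several of neurons and cilia. nlp-22, a neuropeptide gene (WBGene00003760, X, 2341359 to 2342089), fell 14.7-fold, from 93.4 ± 4.53 to 5.44 ± 0.484 (limma adjusted p = 0.0136). The TGF-beta ligand gene daf-7 (WBGene00000903, III, 811828 to 813773) fell 10.1-fold to 3.48 ± 0.839 (0.0203), and the ligand-gated channel gene lgc-46 fell 10.1-fold from 135 ± 54.2 (limma adjusted p = 0.0123). Of 26 neuron genes 4 fell, unc-13 (4.13-fold), ric-4 (3.47-fold), unc-104 (2.71-fold) and unc-10 (2.68-fold), which act in synaptic release and transport, and 6 adjusted over the list alone (median -0.36, camera adjusted p = 0.0232; adjusted p = 0.955 with an estimated correlation). Of 27 cilia genes 3 fell, the ciliary transport genes che-3 (5.25-fold), che-11 (4.17-fold) and dyf-11 (2.98-fold), and 7 adjusted over the list alone (median -0.65, camera adjusted p = 0.0118; adjusted p = 0.535 with an estimated correlation). Other named genes that fell were nas-1 (9.61-fold), srg-8 (11.8-fold) and cyp-13A11 (11.6-fold), and the non-coding genes Y105E8A.40 and C09D8.10 were at least 18-fold and at least 10.4-fold lower. Those that rose included srw-85 (8.94-fold), mjl-1 (7.68-fold), hsp-12.3 (5.55-fold), gex-5 (3.8-fold), folt-1 (3.99-fold, 11.9% of it opposite C06H2.7) and the pseudogene WBGene00023401 (12.7-fold), with limma adjusted p from 0.0427 to 0.0491. Scores of early-development lists, the mean over 4 lists of each list's median log2 value relative to all libraries, were 0.447 and 0.391 in the hpl-2 I158A libraries, -0.111 and -0.014 in N2, and -0.387 and -0.436 in hpl-2. Scores of 5 late lists were -0.154 and -0.145 in hpl-2 I158A, -0.214 and 0.238 in N2, and 0.289 and 0.25 in hpl-2. The lists within a score did not all move alike. The early embryo list stood at 0.128 and -0.002 in hpl-2 I158A and at 0.223 and 0.017 in N2. Cuticle and precuticle stood at 0.242 and 0.158 (N2 -0.059 and 0.102), and body wall muscle at 0.201 and 0.165 (N2 -0.337 and 0.224). The other early lists were above both N2 libraries in both hpl-2 I158A libraries. Of the other late lists, neurons and cilia were below both N2 libraries, while pharynx (-0.204 and -0.037) lay between them (-0.524 and 0.301).

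There were 133 genes higher and 453 lower in hpl-2 I158A than in N2, 586 in all, by limma. That total was 6 without N2 replicate 1, 290 without N2 replicate 2, 5 and 33 without hpl-2 I158A replicates 1 and 2, and 3224 without met-2 set-25 set-32 replicate 2 (1343 higher and 1881 lower, all of the first calls among them). With library class by mitochondrial read share as a term, chosen after seeing the data, 26 were higher and 221 lower. Of these 247, 145 were among the 586. Since that class also held met-2 set-25 set-32 replicate 2, the term does not test mitochondrial share alone. Of 34 named calls, those of C38D9.2 and WBGene00023391 passed with each of the 5 libraries left out, and of the 5 lists oocyte and eggshell and P granule and germline genes did.

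**Figure D2:**
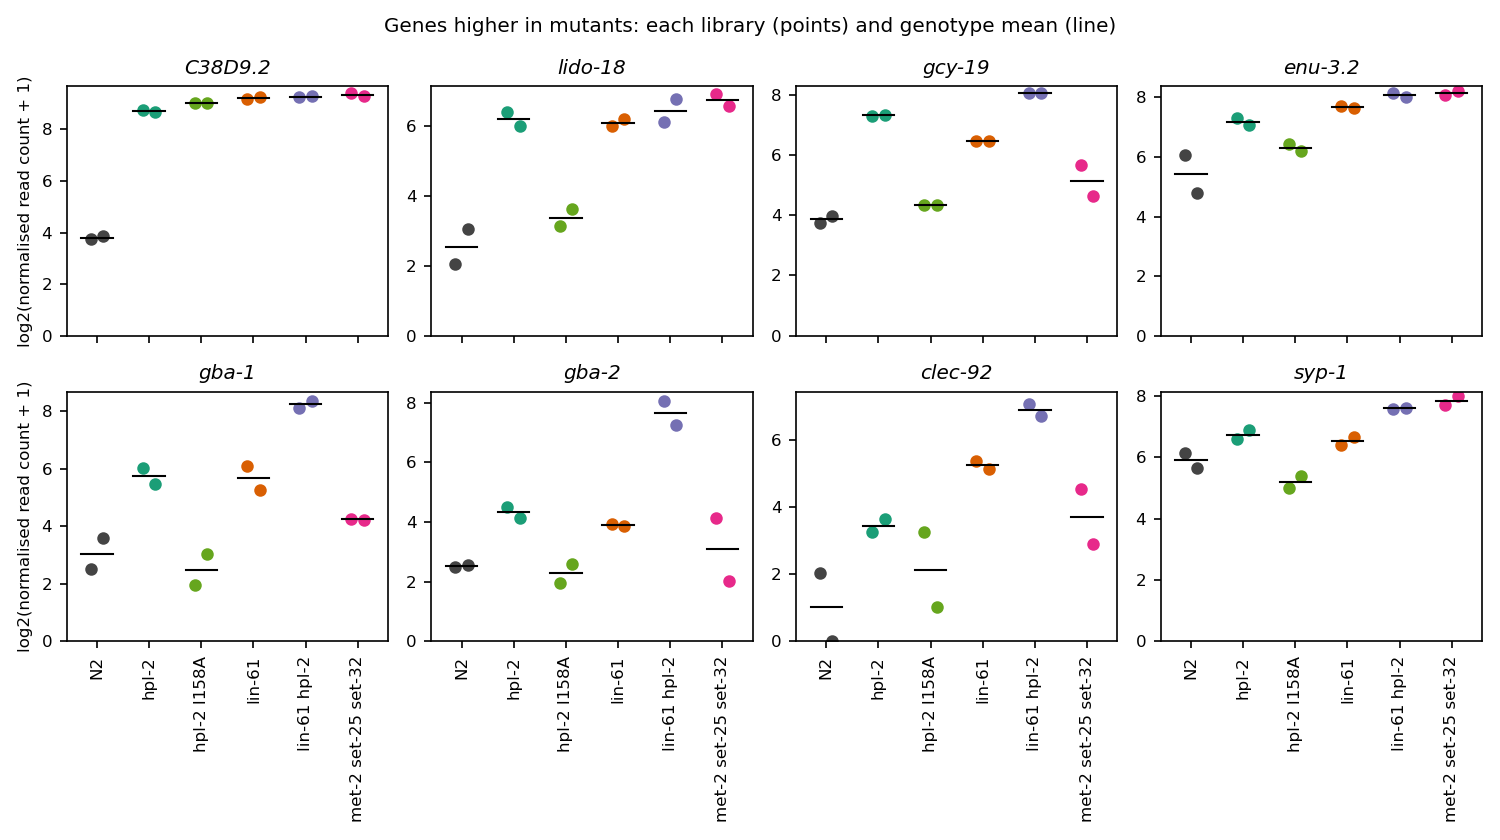
Levels of 8 genes as log2(normalised read count + 1) for each of the 12 libraries; points are libraries, lines are genotype means and columns are genotypes. C38D9.2 lies at 420 or more normalised reads on average in each mutant and at 12.9 in N2.

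In lin-61, which addresses loss of the MBT-repeat reader, gcy-19 rose 6.07-fold, to 87 ± 0.314 (limma adjusted p = 0.0164), and enu-3.2 (WBGene00008003, III, 4783194 to 4785290) rose 4.8-fold, from 46.1 ± 27.3 to 205 ± 8.74 (0.0474). WBGene00014947 was at least 6.84-fold higher (limma adjusted p = 0.015). F23H12.5 (WBGene00009094, V, 12358647 to 12363691) fell from 44 ± 4.97 to 0.454 ± 0.643, a single read in the lin-61 libraries (limma adjusted p = 0.000366). It stood at 42.4 or above in every other genotype, lin-61 hpl-2 included, although lin-61 was at 19.5% of N2 there. Whether this fall belongs to the lin-61 strain rather than to loss of lin-61 was not tested. The non-coding gene F22B3.19 fell 15.3-fold (limma adjusted p = 0.0385). For histones 0 of 57 members were called, with 20 lower and 2 higher adjusted over the list alone (median -0.56, camera adjusted p = 4.53e-14; adjusted p = 0.462 with an estimated correlation). Ribosomal RNA genes took 0.469% and 0.285% of the reads in the lin-61 libraries, and 1.81% and 1.41% in N2. Oocyte and eggshell genes were higher as a list, with 0 called and 0 adjusted over the list alone (median 0.43, camera adjusted p = 4e-06; adjusted p = 0.778 with an estimated correlation). For synMuv B and DREAM factors 0 were called and 1 was lower adjusted over the list alone (median -0.17, camera adjusted p = 0.0468; adjusted p = 0.778 with an estimated correlation). The 3 lists hold 102 genes, of which 37 had an unadjusted limma p under 0.05, DESeq2 called 9 and edgeR 0.

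Altogether 11 genes were higher and 3 lower in lin-61, with 1391 at an unadjusted limma p under 0.05. The total of 14 was 6 and 7 without N2 replicates 1 and 2, 4 without either lin-61 library, and 906 without met-2 set-25 set-32 replicate 2 (454 higher and 452 lower). Calls of C38D9.2, F23H12.5 and WBGene00023391 passed with each library left out, as did the histone list, while oocyte and eggshell genes did not pass without N2 replicate 1 (camera adjusted p = 0.14).

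In the lin-61 hpl-2 double mutant, which addresses loss of both readers, neighbouring gene pairs rose. gba-1 (WBGene00016335, II, 2176741 to 2181990) rose 36.4-fold, from 7.82 ± 4.45 to 300 ± 34.8 (limma adjusted p = 0.00146), and gba-2 (WBGene00016340, II, 2182503 to 2186434) rose 35.2-fold, from 4.77 ± 0.142 to 210 ± 80.7 (0.00761). clec-92 (WBGene00013125, I, 11015486 to 11017497) rose 58.9-fold, to 119 ± 21.6 (0.0192), and its neighbour mltn-2 30.9-fold (limma adjusted p = 0.0457), both from 1.56 ± 2.2. srr-2 rose 28.5-fold (0.0396), and clec-126 was at least 15-fold higher (limma adjusted p = 0.00627). crml-1, a homolog of the actin regulator CARMIL that overlaps a gene on its own strand, fell 6.69-fold, from 200 ± 24.5 to 30.3 ± 13.1 (limma adjusted p = 0.00949), and linc-85 (I, 4295024 to 4296741) had no read and was at least 16.8-fold lower (0.00949).

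Meiosis genes were higher as a list in lin-61 hpl-2: 1 of 30 rose, the synaptonemal complex gene syp-1 (3.23-fold, from 60 ± 14.2 to 194 ± 4.67, limma adjusted p = 0.0304; it overlaps a gene on its own strand), and 5 adjusted over the list alone (median 0.62, camera adjusted p = 7.3e-07; adjusted p = 0.069 with an estimated correlation). Of 53 C-type lectins 2 rose, clec-92 and clec-126, and 5 adjusted over the list alone (median 0.39, camera adjusted p = 0.0244; adjusted p = 0.614 with an estimated correlation). For oocyte and eggshell genes (median 0.43, camera adjusted p = 1.04e-05), collagens (0.29, 0.00451), small RNA pathway (0.21, 0.0244), histones (-0.10, 0.0244) and body wall muscle (-0.23, 0.0244), 0 members were called, and 1 collagen alone when adjusted over the list alone. Their adjusted p was 0.615 for collagens and 0.614 for the others with an estimated correlation. These 5 lists hold 229 genes, of which 39 had an unadjusted limma p under 0.05, DESeq2 called 2 and edgeR 0.

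By limma, 36 genes were higher and 4 lower in lin-61 hpl-2. Their total of 40 was 31 and 19 without N2 replicates 1 and 2, 8 without either lin-61 hpl-2 library, and 730 without met-2 set-25 set-32 replicate 2 (416 higher and 314 lower, all of the first calls among them). Calls of C38D9.2, WBGene00023391, gba-1 and hpl-2 passed with each library left out, as did the meiosis list. Body wall muscle turned higher without N2 replicate 2 (camera adjusted p = 0.734).

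In met-2 set-25 set-32, which addresses loss of the methyltransferases that write the mark, C55C3.3 (WBGene00016953, IV, 5685287 to 5688273) rose 25-fold, from 5.11 ± 3.78 to 138 ± 28.5 (limma adjusted p = 0.00237), and enu-3.2 rose 6.64-fold, to 285 ± 16.3 (0.00628). syp-1 rose 3.84-fold, to 231 ± 32.8 (0.0122), and abt-5, an ABC transporter gene, far-3, a fatty acid and retinol binding protein gene, and fkb-8 rose 7.68-fold, 5.77-fold and 4.64-fold (limma adjusted p = 0.0476, 0.0324 and 0.0227). ethe-1 was at least 5.96-fold higher. T04C12.25, 90.5% of it opposite T04C12.16, rose from 0.779 ± 1.1 to 697 ± 746 (limma adjusted p = 0.0023). Genes at the left end of the X chromosome fell: chkr-1 (WBGene00011612, X, 182691 to 191193) had no read and was at least 95.3-fold lower, from 54.8 ± 32.7 (limma adjusted p = 0.000134), or at least 13.2-fold from the reads of replicate 1 alone. The pseudogene WBGene00008349 (X, 261 to 7587) was at least 91-fold lower and Y73B3A.24 (X, 90282 to 90420), 44.6% of it opposite WBGene00022205, at least 128-fold; from replicate 1 alone the bound was 17.7-fold for Y73B3A.24 and below that of chkr-1 for the pseudogene. Of the 16 expressed genes from X 261 to 207723, 14 stood under 10% of N2 and 7 had no read in either library, while the next expressed gene was R57.2 at 297234 and the 11 genes of the next 200 kb stood at a median of 107% of N2. The transthyretin-like gene ttr-6 fell 14.6-fold (0.00628) and faah-5, 20.7% of it opposite Y56A3A.39, 8.87-fold (limma adjusted p = 0.0476).

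**Figure D3:**
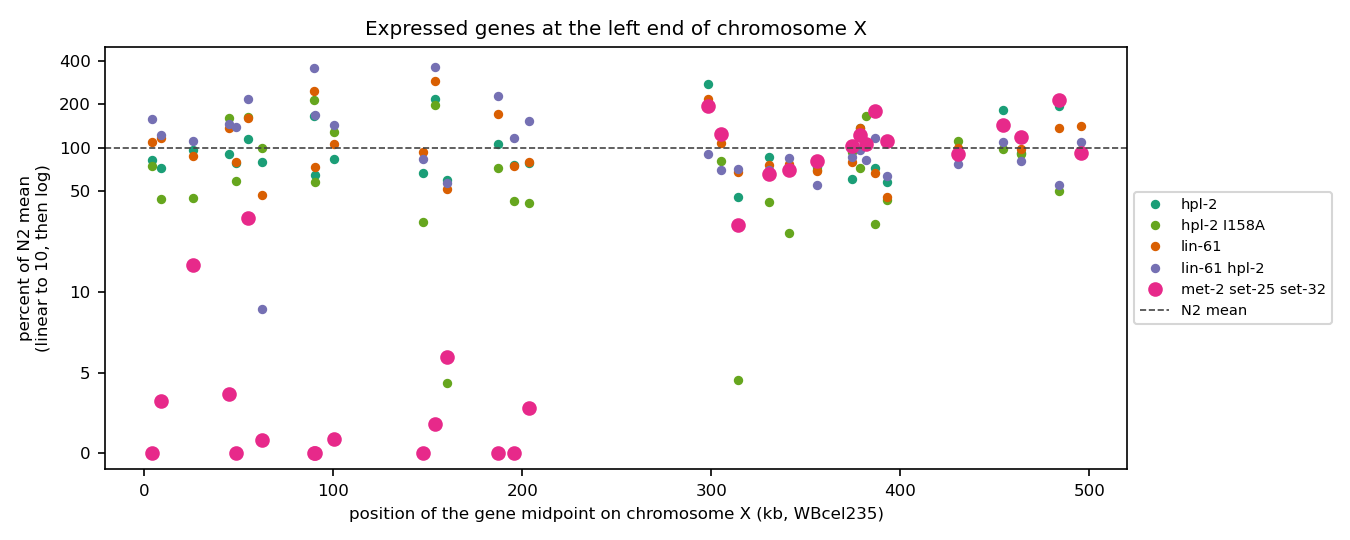
Level of each expressed gene in the first 500 kb of the X chromosome in met-2 set-25 set-32 and the other mutants, as percent of the N2 mean, against position; the vertical axis is linear up to 10 and logarithmic above. In met-2 set-25 set-32 the 16 genes up to position 207723 lie at 32.5% of N2 or lower.

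Of 30 meiosis genes 1 rose in met-2 set-25 set-32, syp-1, and 4 adjusted over the list alone (median 0.51, camera adjusted p = 0.000215; adjusted p = 0.275 with an estimated correlation). For the other 9 lists that passed, 0 members were called. Oocyte and eggshell genes had 6 members adjusted over the list alone (median 0.41, camera adjusted p = 3.14e-05), small RNA pathway 3 (0.44, 0.00012), P granule and germline genes 2 (0.44, 0.000215), MATH and BTB genes 4 of 43 (0.28, 0.00907) and histones 1 lower (-0.37, 3.14e-05). F-box genes (0.39, 0.00852), DNA damage genes (0.24, 0.0202), cilia (0.56, 0.028) and the 87 chemoreceptors (-0.51, 0.00487) had 0 adjusted over the list alone. The adjusted p was 0.58 for MATH and BTB genes, 0.822 for chemoreceptors and 0.638 for the others with an estimated correlation. These 9 lists hold 471 genes, of which 102 had an unadjusted limma p under 0.05, DESeq2 called 7 and edgeR 0. Without replicate 2, whose early-list and late-list scores were 0.33 and 0.228 against -0.085 and 0.06 in replicate 1, only 3 lists passed in this comparison. Meiosis was at camera adjusted p = 0.0111 and histones at 1.42e-07 then, and chemoreceptors and DNA damage genes turned their direction (0.122 and 0.89).

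The counts were 18 higher and 30 lower in met-2 set-25 set-32, 48 in all by limma. That became 31 and 30 without N2 replicates 1 and 2, 5206 without replicate 1 of the mutant and 504 without replicate 2 (253 higher and 251 lower, with 16 and 30 of the first calls among them). With only this mutant and N2 in the fit, 12469 genes were tested and 1 was called. Of 18 named calls 10 passed each time: C38D9.2, C55C3.3, F59C6.15, T04C12.25, WBGene00008349, Y73B3A.24, chkr-1, enu-3.2, lido-18 and met-2. Of the lists, meiosis did.

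**Figure D4:**
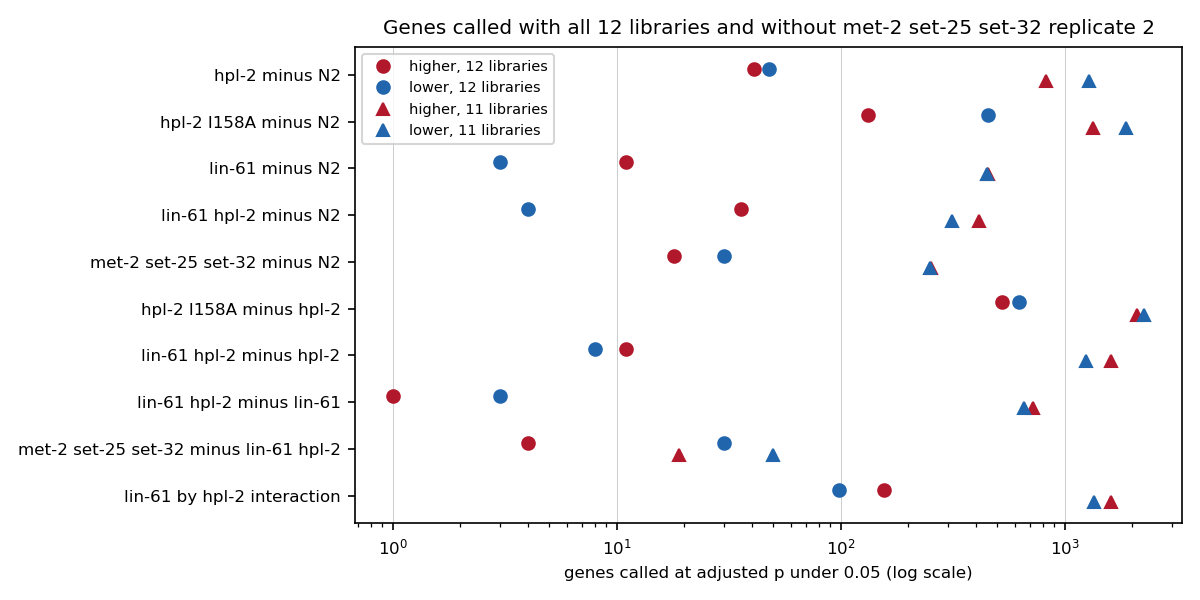
Number of genes called higher and lower by limma in each comparison, on a logarithmic axis, for all 12 libraries (circles) and for 11 libraries without met-2 set-25 set-32 replicate 2 (triangles). For hpl-2 against N2 the 41 higher and 48 lower genes become 829 and 1278.

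hpl-2 I158A and hpl-2 were compared directly to ask whether the point mutant differs from the hpl-2 mutant. Oocyte and eggshell genes were higher in the point mutant, 19 of 27 and 24 adjusted over the list alone (median 1.29, camera adjusted p = 3.89e-16; adjusted p = 0.223 with an estimated correlation). Histones had 25 of 57 higher and 32 adjusted over the list alone (median 0.84, camera adjusted p = 5.1e-16; adjusted p = 0.202 with an estimated correlation), and P granule and germline genes 11 of 24, and 18 higher and 1 lower adjusted over the list alone (1.08, 1.08e-10; adjusted p = 0.419 with an estimated correlation). Cilia genes had 6 of 27 lower and 10 adjusted over the list alone (-0.88, camera adjusted p = 0.000147; adjusted p = 0.202 with an estimated correlation), and neuron genes 6 of 26 and 7 (-0.83, 0.000285; adjusted p = 0.512 with an estimated correlation). hpl-2 itself was 7.25-fold higher in the point mutant (limma adjusted p = 0.00136). The Notch-ligand-family gene dos-3 (10.1% of it opposite K02F3.13) was 8.52-fold higher, madf-10 5.72-fold and kca-1 3.99-fold (limma adjusted p = 0.023, 0.0101 and 0.0323). nas-1, an astacin protease gene, was 21.5-fold lower and chil-25 13.4-fold, and rol-1 and nlp-30 had no read in the point mutant and were at least 21.2-fold and at least 10.2-fold lower. Altogether 526 genes were higher and 622 lower by limma, 1148 in all. This was 3 and 6 without hpl-2 replicates 1 and 2, 2 and 3 without hpl-2 I158A replicates 1 and 2, and 4378 without met-2 set-25 set-32 replicate 2. None of the 8 named calls passed with each library left out, while all 5 lists did.

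Adding the lin-61 mutation to hpl-2 was tested in lin-61 hpl-2 against hpl-2. eef-1A.1, a translation elongation factor gene (WBGene00001168, III, 6970026 to 6972003), rose 2.59-fold, from 8150 ± 259 to 21100 ± 100 (limma adjusted p = 0.0382). gln-6, a glutamine synthetase gene, rose 2.53-fold (0.0382), and snr-2 and rbm-39, lower in hpl-2 than in N2, rose 2.49-fold and 2.35-fold (limma adjusted p = 0.0475 and 0.0382). crml-1 fell 5.93-fold, dao-2 2.45-fold and ttr-16, 40.7% of it opposite lin-3, 2.79-fold, and linc-85 was at least 31.9-fold lower (limma adjusted p = 0.0127). There were 11 genes higher and 8 lower. That total of 19 was 1 and 3 without hpl-2 replicates 1 and 2, 1 and 2 without lin-61 hpl-2 replicates 1 and 2, and 2858 without met-2 set-25 set-32 replicate 2. None of the 8 named calls passed each time.

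As lists, 17 of 29 passed between lin-61 hpl-2 and hpl-2, 13 of them with each library left out. Histones had 1 of 57 higher, and 15 higher and 2 lower adjusted over the list alone (median 0.47, camera adjusted p = 2.73e-06; adjusted p = 0.318 with an estimated correlation). P granule and germline genes had 11 higher and 1 lower adjusted over the list alone (0.70, 2.73e-06; adjusted p = 0.318 with an estimated correlation), oocyte and eggshell genes 7 (0.58, 2.73e-06; adjusted p = 0.318 with an estimated correlation) and meiosis 4 (0.62, 1.87e-05; adjusted p = 0.171 with an estimated correlation). Body wall muscle had 3 lower adjusted over the list alone (-0.48, 1.5e-05), pharynx 1 (-0.52, 0.000303) and neurons 0 (-0.45, 0.000645), each with an adjusted p = 0.318 with an estimated correlation. Intestine genes were at -0.50 (0.024), glutathione S-transferases at -0.89 (0.0293) and nuclear hormone receptors at -0.30 (0.00672), with 0, 0 and 1 members lower adjusted over the list alone and an adjusted p of 0.387, 0.382 and 0.318 with an estimated correlation. The 16 lists other than histones had 0 called members; of their 589 genes 138 had an unadjusted limma p under 0.05, DESeq2 called 20 and edgeR 0.

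Adding the hpl-2 mutation to lin-61 was tested in lin-61 hpl-2 against lin-61. hpl-2 fell 5.89-fold, from 236 ± 3.01 to 40.3 ± 13.4 (limma adjusted p = 0.0061), and linc-85 was at least 17.2-fold lower (0.0436). Just 1 gene was higher and 3 lower by limma, with 1845 at an unadjusted p under 0.05. That total of 4 was 1 without either lin-61 library, 0 and 3 without lin-61 hpl-2 replicates 1 and 2 (DESeq2 called 154 and edgeR 2 with all libraries), and 1380 without met-2 set-25 set-32 replicate 2. Neither named call passed each time. Histones were higher as a list, with 0 called and 10 higher and 2 lower adjusted over the list alone (median 0.35, camera adjusted p = 5.61e-06; adjusted p = 0.778 with an estimated correlation), and so were small RNA pathway genes, with 0 and 0 (0.37, 2.65e-05; adjusted p = 0.778 with an estimated correlation). There were 9 lists that passed, 4 of them with each library left out, and their 300 genes had 0 limma calls, 64 with an unadjusted p under 0.05, 7 DESeq2 calls and 0 edgeR calls. Heat shock genes turned their direction without lin-61 hpl-2 replicate 1 (camera adjusted p = 0.923). Ribosomal RNA genes took 1.65% and 1.36% of the reads in lin-61 hpl-2 and 0.469% and 0.285% in lin-61. Whether the higher histones followed these shares was not tested.

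Mutants of the writers and of both readers were compared in met-2 set-25 set-32 against lin-61 hpl-2. gba-1 and gba-2 were 15.9-fold and 23.8-fold lower in met-2 set-25 set-32, at 17.9 ± 0.153 and 9.87 ± 9.56 (limma adjusted p = 0.0064 and 0.0162). ttr-6 was 17.2-fold lower (0.00465) and chkr-1 at least 220-fold lower (limma adjusted p = 3.42e-05; at least 30.3-fold from replicate 1 of met-2 set-25 set-32 alone). hpl-2 was 8.2-fold higher, crml-1 9.38-fold higher (0.0034) and linc-85 at least 11-fold higher (limma adjusted p = 0.0457), at 19.4 ± 19.6, or at least 18.8-fold and 3.14-fold from replicates 1 and 2 alone. There were 4 genes higher and 30 lower, and their total of 34 was 11 and 13 without lin-61 hpl-2 replicates 1 and 2, 5505 without replicate 1 of met-2 set-25 set-32 and 69 without its replicate 2. With only these 2 genotypes in the fit limma called 0; the fit of all genotypes had 1668 genes at an unadjusted p under 0.05, DESeq2 called 122 and edgeR 32. Calls of chkr-1 and hpl-2 passed each time. Of 15 lists that passed, 5 passed without met-2 set-25 set-32 replicate 2 and body wall muscle each time (median 0.36, 0 called and 0 adjusted over the list alone, camera adjusted p = 5.03e-05; adjusted p = 0.551 with an estimated correlation). Chemoreceptors (-0.87, camera adjusted p = 8.45e-06) and collagens (-0.58, 0.000178) turned their direction without that replicate (0.828 and 0.971), as did P granule and germline genes (0.0308 to 0.262) and small RNA pathway (0.0369 to 0.527). Early embryo genes (0.40, 0.0369), nuclear hormone receptors (0.27, 0.00247) and UDP-glucuronosyltransferases (0.38, 0.0369) were higher as lists, with 0 called and 0 adjusted over the list alone. Every list here other than P granule and germline genes, at 0.578, had an adjusted p = 0.551 with an estimated correlation. The 13 lists without a call hold 563 genes, with 83 at an unadjusted limma p under 0.05, 5 called by DESeq2 and 0 by edgeR.

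The interaction asks whether lin-61 and hpl-2 mutations add up on the log2 scale. xnp-1, a homolog of the chromatin remodeller ATRX (WBGene00006961, I, 4665744 to 4671738), was at 501 ± 327 in N2, 160 ± 34.1 in hpl-2, 136 ± 21.5 in lin-61 and 646 ± 347 in lin-61 hpl-2, a departure of 3.63 (SE 0.634, limma adjusted p = 0.0259). rad-50, a break repair gene, departed by 3.21, the dosage compensation gene sdc-2 (in part opposite anr-16) by 3.04 and lpd-2 by 2.82. lido-18 departed by -3.29, at 72.8 ± 14.1, 67 ± 6.72 and 87.7 ± 28 in the 3 mutants, and eppl-1 by -3.25. linc-85 departed by -5.88, with no read in lin-61 hpl-2, and mpz-6 by -5.63, with no read in N2, so that both values depend on the added count of 1. Histones departed upwards, 11 of 57 with 2 downwards and 27 and 3 adjusted over the list alone (median 1.10, camera adjusted p = 2.85e-12; adjusted p = 0.335 with an estimated correlation). Small RNA pathway genes had 2 of 38 and 7 adjusted over the list alone (0.56, 3.32e-05; adjusted p = 0.52 with an estimated correlation), and glutathione S-transferases 0 and 0 (-1.12, 0.0206; adjusted p = 0.52 with an estimated correlation). Ribosomal RNA genes took 1.81% and 1.41% of the reads in N2 and 1.65% and 1.36% in lin-61 hpl-2. They took 0.469% and 0.285% in lin-61 and 2.37% and 0.372% in hpl-2. Whether the histone departures followed these shares was not tested. There were 156 genes above and 98 below additivity. That total of 254 was 13 and 129 without N2 replicates 1 and 2, 8 and 3 without hpl-2 replicates 1 and 2, 4 without either lin-61 library, 4 and 12 without lin-61 hpl-2 replicates 1 and 2, and 2954 without met-2 set-25 set-32 replicate 2. None of the 8 named calls passed each time, and 6 of the 12 lists did, histones and small RNA pathway among them. Mitochondrial read share was higher in N2 and lin-61 hpl-2 than in lin-61, but in hpl-2 it was 0.446% in replicate 1, above both N2 libraries, and 0.104% in replicate 2. With it as a class term 3 genes were called. That class also held met-2 set-25 set-32 replicate 2, so this count cannot show that the class accounts for the calls.

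**Figure D5:**
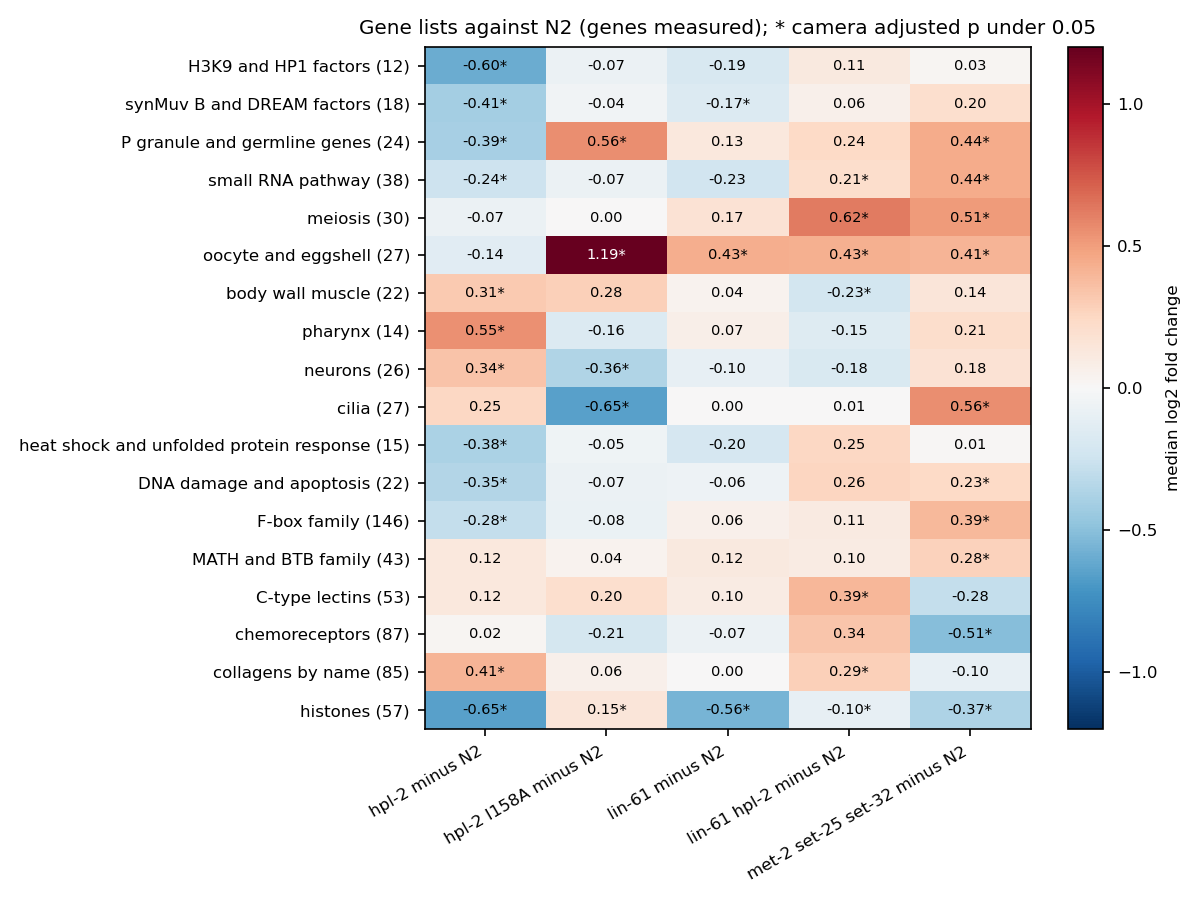
Median log2 fold change of each gene list (vertical) in each comparison with N2 (horizontal), for 18 lists that passed in at least 1 of these comparisons; colour gives the median and a star marks a camera adjusted p under 0.05. Oocyte and eggshell genes reach 1.19 in hpl-2 I158A and histones -0.65 in hpl-2.

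Lists that passed in no comparison were spermatogenesis (8 measured, lowest camera adjusted p = 0.134), cuticle and precuticle (29, 0.0585), intracellular pathogen response (6, 0.152), innate defence effectors (12, 0.0786), cytochromes P450 (30, 0.134) and pals (7, 0.324). With an estimated correlation 0 of the 29 lists passed in any comparison.

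Positions on autosomes were tested because H3K9 methylation in this species lies mainly on chromosome arms. Of the genes lower in hpl-2 and on autosomes, 40 lay on arms and 6 in centres, 87% against 58.5% of the genes tested (odds ratio 4.75, Fisher's exact test, adjusted p = 0.000182). With a CPM of at least 1 as the filter these were 14 and 3 and did not pass (odds ratio 3.01, Fisher's exact test, adjusted p = 0.276). Of those higher in lin-61 hpl-2, 30 lay on arms and 4 in centres (88.2%, odds ratio 5.34, Fisher's exact test, adjusted p = 0.00107). Of those lower in hpl-2 I158A, 45% lay on arms (odds ratio 0.569, Fisher's exact test, adjusted p = 5.7e-07). The other 7 odds ratios did not pass for limma calls in all 12 libraries. For DESeq2 calls, those of genes higher in hpl-2 (0.516) and in met-2 set-25 set-32 (2.18) passed (Fisher's exact test, adjusted p = 0.00612 and 0.0106). Without met-2 set-25 set-32 replicate 2 the 3 odds ratios were 1.85, 1.96 and 0.65, and that of genes higher in hpl-2 was 0.564 in place of 0.671 and passed (Fisher's exact test, adjusted p = 1.96e-12). Of 30 genes lower in met-2 set-25 set-32, 17 lay on the X chromosome (odds ratio 7.23, Fisher's exact test, unadjusted p = 2.31e-07) and 7 were pseudogenes (Fisher's exact test, adjusted p = 1.8e-05). Of these, 13 and 6 belong to the run at the left end of X. Without replicate 2 of this mutant, which leaves a lone library in the genotype, the odds ratios were 2.45 for the X chromosome and 2.21 for pseudogenes. How many of the genes called then lay in the run, with its 16 expressed genes and 9 pseudogenes, was not counted. The pseudogene result is therefore not shown to hold beyond the run.

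The responses of different mutants were compared across genes, which are not independent replicates. Log2 fold changes of hpl-2 and lin-61 correlated at 0.682, those of hpl-2 I158A and lin-61 at 0.559 and those of lin-61 hpl-2 and met-2 set-25 set-32 at 0.527, the highest of 10 pairs, and the lowest was 0.26. Unchanged groups simulated with shared control libraries correlated at 0.502, above 7 of the 10 pairs. The pair of hpl-2 and hpl-2 I158A (0.367) was among these 7. That simulated value follows from equal spreads and a shared control. The median SD of log2 values between replicates was 0.297 in N2, 0.157 in hpl-2 and 0.165 in lin-61. A control that spreads more than the mutants raises the correlation of unchanged groups, so a pair above 0.502 is not thereby shown to be similar. Changes private to each mutant lower a correlation, so a pair below the simulated value is not shown to be dissimilar. The covariances of the 3 pairs with the highest correlations were 0.355, 0.339 and 0.333, and that of hpl-2 and hpl-2 I158A was 0.249. The simulated covariance was 0.0959, and that from the spread of the N2 libraries was 0.185. hpl-2 and lin-61 shared 9 higher genes, with 0.031 for independent lists of these sizes, a figure that ignores the shared N2 libraries. The simulations gave 0 shared genes, but their unchanged groups had no gene called at all, so this sets no expectation for lists of changed genes. hpl-2 and hpl-2 I158A shared 15 (0.37 for independent lists), and lin-61 hpl-2 and met-2 set-25 set-32 shared 8 (0.044). With 1 N2 library for each mutant, a split chosen after seeing the data, the 3 correlations were 0.243, 0.196 and 0.188 as means of both ways round, with covariances of 0.171, 0.154 and 0.148, and the correlations of the other 7 pairs ran from -0.0103 to 0.0802. Each side of the split holds a single library, and part of the excess in the shared genes may come from the shared controls.

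In the authors' deposited table, genes with an adjusted p under 0.05 numbered 166 higher and 319 lower in hpl-2, 292 and 818 in hpl-2 I158A, 79 and 79 in lin-61, 84 and 17 in lin-61 hpl-2, and 98 and 228 in met-2 set-25 set-32. Between mutants the authors' deposited table gave 868 higher and 908 lower for hpl-2 I158A against hpl-2, 452 and 219 for lin-61 hpl-2 against hpl-2, 149 and 91 for lin-61 hpl-2 against lin-61, and 28 and 133 for met-2 set-25 set-32 against lin-61 hpl-2.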

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

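Of the tests in this part, the comparison of oocyte genes with histones in lin-61, the fit with library class as a term and the values without met-2 set-25 set-32 replicate 2 were chosen after the result was seen. The effect of one mutation differed with the other mutation present, by the limma test of the interaction of lin-61 and hpl-2: 156 genes lay above additivity and 98 below. Those named were xnp-1 (3.63), rad-50 (3.21), sdc-2 (3.04), lpd-2 (2.82), eppl-1 (-3.25), lido-18 (-3.29), mpz-6 (-5.63) and linc-85 (-5.88), as log2 departures. The total of 254 was 13 and 129 without N2 replicates 1 and 2, 8 and 3 without hpl-2 replicates 1 and 2, 4 without either lin-61 library, 4 and 12 without lin-61 hpl-2 replicates 1 and 2, and 2954 without met-2 set-25 set-32 replicate 2. With library class as a term 3 genes were called. That class sets N2, lin-61 hpl-2, hpl-2 replicate 1 and met-2 set-25 set-32 replicate 2 apart from the rest. It overlaps with the interaction in part. With genotype in the fit, the term rests only on hpl-2 and met-2 set-25 set-32, whose replicates fall in different classes. It therefore takes up part of the deviation of met-2 set-25 set-32 replicate 2 and cannot show that the class accounts for the calls.

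Marker lists moved together between genotypes, and embryos of different age might lie behind this. Over the 12 libraries, scores of early and late lists correlated at -0.485 (permutation p = 0.112; Spearman -0.448, p = 0.146), at -0.698 (permutation p = 0.0166; Spearman -0.545, p = 0.0882) without met-2 set-25 set-32 replicate 2 and at -0.279 without both hpl-2 I158A libraries; the permutations take replicates as independent, and within genotypes both scores differed in opposite directions in 1 of 6, so age cannot be told apart from genotype with 2 libraries in each. Age as the whole cause stays open in lin-61: the medians of oocyte genes and histones, both high in early embryos, lay 0.993 apart in opposite directions, but the oocyte list did not pass without N2 replicate 1 (camera adjusted p = 0.14). RNA without a poly(A) tail, carried through in different amounts, is argued against as the whole cause of the lower histones of hpl-2. The 2 hpl-2 libraries differed by 0.128 in median histone log2, with ribosomal shares of 2.37% and 0.372%. The library with the larger share had the higher histones (-0.53 against -0.66 over N2), so a part in the difference stays open. This rests on 2 libraries, with the ribosomal share as the only measure of such RNA. For the lower histones of lin-61 (0.469% and 0.285%) it was not tested. An effect of genotype on these genes, or on the pace of development, stays open and untested.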

How the results depend on the processing

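The fits with edgeR, a value of at least 20, genes without exons opposite another gene, library class, 1 N2 library for each mutant and without met-2 set-25 set-32 replicate 2 where it is not compared were chosen after seeing the data. Of 2209 values of log2 fold changes under other settings 1578 kept direction and side of the threshold, 605 were weaker (359 of them with a library left out), 12 stronger and 14 reversed. Of 878 list values 658 kept both, 211 were weaker (98 with a library left out) and 9 reversed. Where a count or direction moved, the cause was not tested. Fits with fewer libraries have fewer residual degrees of freedom, yet several of them called more genes. Without met-2 set-25 set-32 replicate 2 the residual degrees of freedom were 5 and the prior degrees 9.21, against 6 and 4.73.

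Counts of calls are given in the order hpl-2 (89), hpl-2 I158A (586), lin-61 (14), lin-61 hpl-2 (40), met-2 set-25 set-32 (48), hpl-2 I158A against hpl-2 (1148), lin-61 hpl-2 against hpl-2 (19) and against lin-61 (4), met-2 set-25 set-32 against lin-61 hpl-2 (34) and the interaction (254). Only the compared genotypes in the fit gave 481, 1916, 152, 73, 1, 6116, 3445, 1971, 0 and 2569. For that 0 by limma, the fit of all genotypes had 1668 genes at an unadjusted p under 0.05, DESeq2 called 122 and edgeR 32. Library class as a term gave 29, 247, 4, 75 and 689 against N2, then 3 in lin-61 hpl-2 against hpl-2, 0 against lin-61 (limma; 1845 at an unadjusted p under 0.05 without the term, DESeq2 154, edgeR 2) and 3 in the interaction. DESeq2 gave 284.0, 893, 88, 95 and 226 against N2, then 430, 154, 122 and 610 in the last 4. edgeR gave 38 in hpl-2, 362 in hpl-2 I158A, 24 in lin-61 hpl-2, then 6 against hpl-2 and 2 against lin-61. No low-value filter gave 31 in hpl-2, 260 in hpl-2 I158A, 28 in met-2 set-25 set-32, 489 in hpl-2 I158A against hpl-2, 3 and 2 in lin-61 hpl-2 against hpl-2 and lin-61, and 78 in the interaction.

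TMM scaling gave 59 in hpl-2 (33 higher and 26 lower, against 41 and 48). A CPM of at least 1 gave 47 in hpl-2, 7 in lin-61 hpl-2 against hpl-2 and 165 in the interaction. Pseudocount 5 gave 61 in lin-61 hpl-2 and 97 against hpl-2. A value of at least 20 gave 79 in lin-61 hpl-2 against hpl-2 and 386 in the interaction. Genes without exons opposite another gene gave 216 in hpl-2, 43 in lin-61, 73 in met-2 set-25 set-32, 293 and 54 in lin-61 hpl-2 against hpl-2 and lin-61, and 439 in the interaction. The replicate block gave 30 in hpl-2, 4 in lin-61 hpl-2 against hpl-2 and 130 in the interaction, and kept 93 of 95 list calls. The 15 correlations of same-numbered deviations ran from -0.077 to 0.16, the highest between N2 and met-2 set-25 set-32. No strong pairing by number was seen, but low correlations cannot show that same-numbered libraries share no day or batch.

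With 1 library left out, counts ran from 8 to 2107 in hpl-2, 5 to 3224 in hpl-2 I158A, 4 to 906 in lin-61, 8 to 730 in lin-61 hpl-2, 30 to 5206 in met-2 set-25 set-32, 2 to 4378 in hpl-2 I158A against hpl-2, 1 to 2858 and 0 to 1380 in lin-61 hpl-2 against hpl-2 and lin-61, 11 to 5505 in met-2 set-25 set-32 against lin-61 hpl-2, and 3 to 2954 in the interaction. The lone library left is assumed to vary like the other genotypes.

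Odds ratios on arms moved from 0.671 to 0.516 (DESeq2) and 0.564 (without met-2 set-25 set-32 replicate 2) for genes higher in hpl-2, both of which passed (Fisher's exact test, adjusted p = 0.00612 and 1.96e-12), from 4.75 to 3.01 (CPM; it no longer passed, Fisher's exact test, adjusted p = 0.276) for those lower, from 5.34 to 11 (DESeq2) for those higher in lin-61 hpl-2, and from 1.42 to 2.18 (DESeq2; it then passed, Fisher's exact test, adjusted p = 0.0106) for those higher in met-2 set-25 set-32. None of those that turned passed its test: 1.06 to 0.813 and 0.355 to 1.16 for higher and lower in lin-61 without met-2 set-25 set-32 replicate 2, 2.13 to 0.495 for lower in lin-61 hpl-2 with other bounds for the arms, and 0.608 to 1.09 for lower in met-2 set-25 set-32 with DESeq2. For pseudogenes among higher calls, hpl-2 turned from 1.59 to 0.94 without that library and hpl-2 I158A from 0.941 to 1.21 at an absolute log2 fold change of at least 1, and without that library hpl-2 I158A was at 0.396, lin-61 hpl-2 at 1.74 and met-2 set-25 set-32 at 2.4, and these 3 then passed. The correlation of hpl-2 I158A and met-2 set-25 set-32 moved from 0.26 to 0.357 (CPM). With 1 N2 library for each mutant, hpl-2 correlated with hpl-2 I158A, lin-61, lin-61 hpl-2 and met-2 set-25 set-32 at 0.0759, 0.243, 0.0762 and 0.035, hpl-2 I158A with the last 3 at 0.196, 0.00373 and 0.0142, lin-61 with the last 2 at 0.0802 and -0.0103 (turned from 0.304), and lin-61 hpl-2 with met-2 set-25 set-32 at 0.188.

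Log2 fold changes that turned belonged to mutated genes that were not called. lin-61 in hpl-2 went from 0.01 to -0.062 (DESeq2), -0.042 (edgeR) and -0.19 (without hpl-2 replicate 1), with libraries left out from -0.558 (N2 replicate 2) to 0.573 (N2 replicate 1). hpl-2 in hpl-2 I158A, at -0.05, ran from -0.209 (without N2 replicate 2) to 0.115 (without N2 replicate 1) and was 0.061 without hpl-2 I158A replicate 2. With library class, lin-61 in hpl-2 I158A went from -0.09 to 0.773, set-32 from 0.70 to -0.242, set-25 from 0.18 to -0.077, and set-32 in lin-61 from 0.11 to -0.836. With libraries left out, lin-61 in hpl-2 I158A ran from -0.657 (N2 replicate 2) to 0.473 (N2 replicate 1), set-32 in lin-61 from -0.056 (lin-61 replicate 2) to 0.27 (lin-61 replicate 1), and lin-61 in met-2 set-25 set-32, at 0.33, from -0.343 (replicate 2 of the mutant) to 0.993 (replicate 1), with -0.24 without N2 replicate 2.

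With libraries left out, the camera adjusted p of lists that turned ran from 2.66e-06 (without N2 replicate 2) to 0.901 (without N2 replicate 1, turned) for body wall muscle in hpl-2, and from 3.14e-06 (without N2 replicate 1) to 0.734 (without N2 replicate 2, turned) in lin-61 hpl-2. Heat shock genes in lin-61 hpl-2 against lin-61 ran from 5.32e-08 (without lin-61 hpl-2 replicate 2) to 0.923 (without replicate 1, turned). In met-2 set-25 set-32 the list turned without replicate 2 and the lowest p was without replicate 1: 0.00251 to 0.89 for DNA damage genes and 8.76e-06 to 0.122 for chemoreceptors against N2 (0.183, unturned, without N2 replicate 1), and 0.00242 to 0.262 for P granule genes, 0.00526 to 0.527 for small RNA pathway and 2.25e-07 to 0.828 for chemoreceptors against lin-61 hpl-2. Collagens there ran from 9.12e-06 (without lin-61 hpl-2 replicate 2) to 0.971 (without met-2 set-25 set-32 replicate 2, turned).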

Other observations

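In this part, the tests of neighbouring genes, of met-2 set-25 set-32 replicate 2 and of the X chromosome were chosen after the result was seen, and the 2 tests of antisense genes before. Genes higher in lin-61 hpl-2 lay in neighbouring pairs: beside gba-1 and gba-2 and clec-92 and mltn-2, the called pairs were srr-2 and oac-49, C55C3.6 and C55C3.3, F08A8.8 and F08A8.5, and 21ur-12557 and F40D4.13. The partners outside the naming rule were chosen after their values were seen. There were 6 pairs within 10 kb among the 36 higher genes, and at most 4 in 10000 random sets of tested genes (permutation p = 1e-04, the smallest possible). That neighbouring genes change together in this mutant is a hypothesis found and tested on the same data.

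Non-coding genes antisense to exons held more reads per kb than the coding genes opposite them, and met-2 set-25 set-32 replicate 2 stood apart in this. Libraries counted on the strand opposite to the transcript are a possible explanation of the first: across pairs the 2 genes' log2 fold changes correlated at 0.674 in hpl-2 I158A against hpl-2, the comparison chosen beforehand and the highest of 7 (lowest 0.396), though pairs opposite introns also correlated there (0.384, at most 0.127 when shuffled). Transcription of the non-coding genes themselves, as the whole cause, was predicted to leave both kinds alike, but those opposite exons lay a median log2 of 3.42 above those opposite introns. Both kinds are different genes whose own transcription may differ, so this gap does not exclude it. Whether replicate 2 kept less of its strand information stays open: over replicate 1 its coding genes gained a median log2 of 3.03 more than antisense genes, but that follows from the low share of non-coding genes seen first. That share, 3.2%, excludes deeper sequencing of the same kind of library alone, and the genotype is excluded because replicate 1 had 17.5%, above each library of the other genotypes, the lowest of which had 14.5%. How the authors set the strand in counting stays open. If it was opposite to the transcript, levels of all coding genes, not only of overlapping ones, would rest on reads of the wrong strand.

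Genes at the left end of the X chromosome had few or no reads in met-2 set-25 set-32, and a strain lacking this end could give that. Of the run's 16 expressed genes 87.5% lay under 10% of N2, but 2 pseudogenes, WBGene00021342 and WBGene00022219, kept 15.6% (3.57% and 27.5% in replicates 1 and 2, on 1 and 48 reads) and 32.5% (47.9% and 17.1%, on 9 and 20 reads); 14 of the 16 lay under 10% in either replicate alone too, so this cannot be told apart from other causes with expression values alone. Lower expression of single genes, each on its own, is argued against by the run of 16 neighbours under 50% of N2. At most 7 occurred in 1000 shuffled orders (permutation p = 0.000999, the smallest possible). Runs of 11 in hpl-2 I158A, 9 in hpl-2 and 7 in lin-61 also exceeded their own shuffled orders, with the same permutation p. That p therefore does not single out the end of X, though its run was the longest. Under 10% of N2 the run held 10 neighbours, against at most 3 when shuffled and 4 in another mutant. Too few reads are excluded, with 3070 expected in replicate 2 at the N2 level and 78 found. Lower expression of the whole region in this genotype stays open and untested.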
